A study of Homo sapiens with 6 samples.

How the data were processed

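Gene expression was measured on Affymetrix arrays in MDA-MB-231 cells, a human triple-negative breast cancer line. The labels describe 2 groups of 3 arrays each, DMSO vehicle and YW3-56, and call the replicates biological. Cells were grown in medium with 10% serum at 37 °C and treated at about 70% confluence, per the labels' protocols. The labels give 10 µM and 8 h for YW3-56 and do not state a time for the vehicle separately. Total RNA was purified on silica spin columns and the complementary DNA was labelled with biotin in a whole-transcript protocol, per the labels' protocols.

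The deposited table holds log2 expression values for 33297 probe sets in 6 columns, 1 per array, and every column was matched to its sample. Per the submitters' processing notes, the authors used RMA and the affy package, whose versions are not given in the sources used here. RMA corrects background, equalises the distribution of probe intensities between arrays and summarises the probes of a set. Because the distributions are equalised, a shift of all transcripts in 1 direction would not be visible in these values. The deposited values ran from 1.91 to 14.69, and array medians over all probe sets ran from 7.55 to 7.74. No value was missing and no pair of arrays was identical. Arrays carry no read depth, so the number of arrays limits the precision.

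Probe sets were named from the platform annotation given with the table, which can be old. A single gene symbol was listed for 19460 probe sets, several symbols for 1754 and none for 12083. Of the probe sets with a single symbol, 19429 matched a RefSeq gene (assembly GRCh38.p14) by Entrez identifier, 31 did not, and 0 symbols needed an update. That assembly was used for names, host genes, chromosomes and lengths of small RNA genes only, since the build of the array annotation is not given in the sources used here. Probe sets with several or no symbols were left out of the gene-level tests. For the 769 genes with more than 1 probe set, the probe set with the highest mean over the 6 arrays stood for the gene, which gave 18417 genes.

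YW3-56 was compared with DMSO with limma 3.58.1 in R 4.3.3, using lmFit and eBayes on the deposited log2 values with group as the only term, no filter on dim genes and no further normalization. Tests were two-sided, and p-values were adjusted by the Benjamini-Hochberg method over all genes tested. A gene was called changed at an adjusted p under 0.05, and an additional count required at least a 2-fold change. The fit left 4 residual degrees of freedom, and eBayes added 4.17 prior ones. Fold changes are differences of group means on the log2 scale, given with their standard error (SE), and levels are given as mean and standard deviation (SD) over arrays.

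The groups, the main design, the alternatives, the rule for named genes and 31 gene lists were fixed before the data were examined. Of 722 list entries, 665 were measured. Lists with at least 5 measured members were tested with limma's camera at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over 30 lists. Camera with an estimated correlation and fry were run beside it. The result of 1 tested list is not reported here, although the counts of lists include it. Counts of members are given over all genes tested and adjusted over the list alone. Enrichment of 20 symbol families among calls, in each direction, was tested with Fisher's exact test, two-sided, against all other tested genes and adjusted over families and directions.

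Genes were named by a rule. It took the 10 largest rises and 10 largest falls among called genes whose groups did not overlap, passing over symbols beginning LOC, MIR or SNOR. It added ATF4, DDIT3, SESN2, TRIB3, CHAC1, ASNS, DDIT4, HSPA5 and SQSTM1, all measured PADI genes, and up to 4 members of each list with the largest change, called members first. The rule named 136 genes, of which 116 were called, and in all 116 the 3 treated arrays lay on 1 side of the 3 DMSO arrays. List members named beyond this rule to fill a small count, and the small nucleolar RNA and zinc finger genes given as examples, were chosen after their values were seen.

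The replicate numbers in the labels were checked as a pairing. Deviations from the group means correlated over genes at 0.54 between DMSO replicate 1 and YW3-56 replicate 1, at 0.37 between the arrays numbered 2 and at 0.10 between those numbered 3. The check was planned without a bound. Each pair exceeded 0.1, the bound used for shared handling, which was written after the result was seen. The last value is only 0.102, and YW3-56 replicate 2 correlated better with DMSO replicate 3, at 0.42, so the pairing stays uncertain. A fit with replicate number as a block was therefore run as an alternative.

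Other alternatives were a second quantile normalization, centring of each array on its median, 2 filters on dim genes, the mean of a gene's probe sets, all probe sets tested as such, a trended and robust prior, array weights, Welch's test per gene, each array left out in turn, an adjusted p of 0.01, limma's treat at 1.2-fold, lists without members of the ATF4 list, lists restricted to brighter members, and families tested among brighter genes. The fits were tested on simulated data with the arrays' own variances, 18417 genes and 200 changed genes. There, 57% of 1.5-fold and 86% of 2-fold changes were recovered, with 5 calls among unchanged genes. The simulated noise was independent for each gene, and far fewer genes changed than were called in the data. The rates therefore need not hold for the real comparison. Tables and figures were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.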

Results

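Expression was measured in 6 cultures of MDA-MB-231, a human triple-negative breast cancer cell line. In 3 cultures the cells received the vehicle DMSO, and in 3 they received 10 µM YW3-56 for 8 h. YW3-56 is known as a small-molecule inhibitor of peptidylarginine deiminases (PADs), enzymes that convert arginine in proteins to citrulline. The design asks which transcripts differ after exposure to the compound. Values were the deposited RMA expression values on the log2 scale for 18417 genes, and the 3 arrays in each group set the precision of every difference given here.

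Arrays of 1 group resembled each other more than arrays of different groups. Over genes, Pearson correlations ran from 0.990 to 0.997 within groups and from 0.980 to 0.985 between groups. The first principal component held 64.2% of the variance and separated DMSO from YW3-56. On the second, with 21.9%, DMSO replicate 1 scored 22.2 and YW3-56 replicate 1 scored 9.77, while the other 4 arrays had scores below 0. The median SD of a gene between arrays was 0.12 in DMSO and 0.09 in YW3-56 on the log2 scale.

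**Figure D1:**
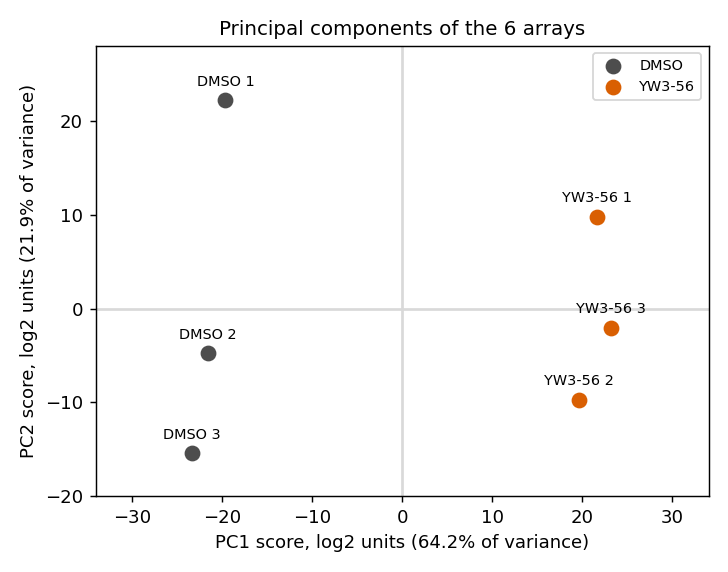
Scores of the 6 arrays on the first (x axis, 64.2% of variance) and second (y axis, 21.9%) principal components of the log2 values, 1 point per array coloured by group. The 3 DMSO arrays lie left of 0 and the 3 YW3-56 arrays right of 0, and DMSO replicate 1 has the highest score on the second component, 22.2.

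In cells treated with YW3-56, 23 of 31 measured genes of the list for ATF4, a stress transcription factor, and the integrated stress response were higher. So were 16 of 17 heat shock genes, while 25 of 27 ribosome biogenesis genes and 18 of 30 mitotic genes were lower. Camera called these lists with a preset correlation and none of them with an estimated one (adjusted p = 0.195 for the ATF4, heat shock and ribosome biogenesis lists and 0.38 for mitosis). HSPA6, a stress-inducible HSP70 chaperone, was 31.1-fold higher (log2 fold change 4.96 ± 0.17 SE, n = 3 arrays per group, limma adjusted p = 5.7e-06). HMOX1, the haem-degrading enzyme haem oxygenase 1, was 9.38-fold higher (3.23 ± 0.11), and DDIT3, the stress transcription factor CHOP, was 10.3-fold higher (3.36 ± 0.12). Among the genes that fell, TFRC, the transferrin receptor, was 3.28-fold lower (-1.71 ± 0.15), and RRS1, a ribosome assembly factor, was 2.95-fold lower (-1.56 ± 0.09). The probe sets behind these genes were 7906764 for HSPA6, 8072678 for HMOX1, 7964460 for DDIT3, 8093053 for TFRC and 8146685 for RRS1.

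At an adjusted p under 0.05, limma called 3933 of 18417 genes, or 21.4%, with 1812 higher and 2121 lower in YW3-56. At least 2-fold changes were called for 262 genes, 165 higher and 97 lower, so the large changes were more often rises. The 3 treated values lay entirely above or below the 3 DMSO values for 6804 genes, 36.9% of those tested, against the 10% that chance gives. Most calls were small, with 2759 under 1.5-fold. Leaving out YW3-56 replicate 3 lowered the count to 2364, leaving out YW3-56 replicate 2 lowered the falls to 1309, and a per-gene test without shared variance called 1130. That test also ended the calls of 70 of the 116 called named genes, which include genes beyond those given with its p-value. Array weights raised the count to 6079, with 3432 lower. They gave DMSO replicate 2 a weight of 2.94, against 0.33 for DMSO replicate 1 and 0.65 for DMSO replicate 3. The balance of directions turned with scaling, to 1899 higher and 1742 lower after centring of each array and to 2120 and 2091 after a second quantile normalization.

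The 10 largest rises covered several stress systems. After HSPA6 came NMRAL2P (3.66 ± 0.22), a transcribed pseudogene, then DDIT3 and HMOX1, and then DNAJB4 (2.63 ± 0.15), a co-chaperone of HSP70. CLU, the secreted chaperone clusterin, SAT1, the enzyme that acetylates spermidine and spermine, and SESN2, an inhibitor of mTORC1, each rose by 2.61 on the log2 scale, with SE of 0.08, 0.09 and 0.15. CHAC1, which degrades glutathione, rose by 2.52 ± 0.41, and ZFAND2A, an arsenite-inducible regulator of the proteasome, was 5.65-fold higher. Adjusted p-values of these 10 genes lay between 5.5e-06 and 0.0034. HSPA6 closely resembles other HSP70 genes in sequence, and probes shared between such copies cannot be separated here.

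The 10 largest falls, after the passing over of small nucleolar RNA genes, began with the histone gene H2AC15 (-1.95 ± 0.26) and the spliceosomal RNA gene RNU5D-1 (-1.84 ± 0.28). RNU5D-1 was dim, with a mean of 4.31 ± 0.65 SD in YW3-56 and a mean over all arrays at the 3.06 percentile of tested genes, so its size is uncertain. TFRC followed, then TFAP2C (-1.69 ± 0.12), which encodes the transcription factor AP-2 gamma, and PTX3 (-1.69 ± 0.15), a secreted pattern recognition protein. F3, the tissue factor that starts coagulation, changed by -1.66 ± 0.18, ADORA2B, an adenosine receptor, by -1.58 ± 0.11, and RRS1 by the value given above. NOG, the BMP antagonist noggin (-1.55 ± 0.12), and the U1 RNA variant RNVU1-19 (-1.49 ± 0.18) completed the group. The adjusted p-values of these 10 lay between 7.5e-05 and 0.0028, and H2AC15 belongs to a family of near-identical histone genes. A per-gene test without shared variance kept the calls of TFRC and ADORA2B among these falls and lost those of H2AC15, RNU5D-1, TFAP2C, PTX3, F3, RRS1, NOG and RNVU1-19, with adjusted p from 0.0505 for RRS1 to 0.143 for RNU5D-1. Among the 10 largest rises it lost those of NMRAL2P (0.0642) and CHAC1 (0.175).

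**Figure D2:**
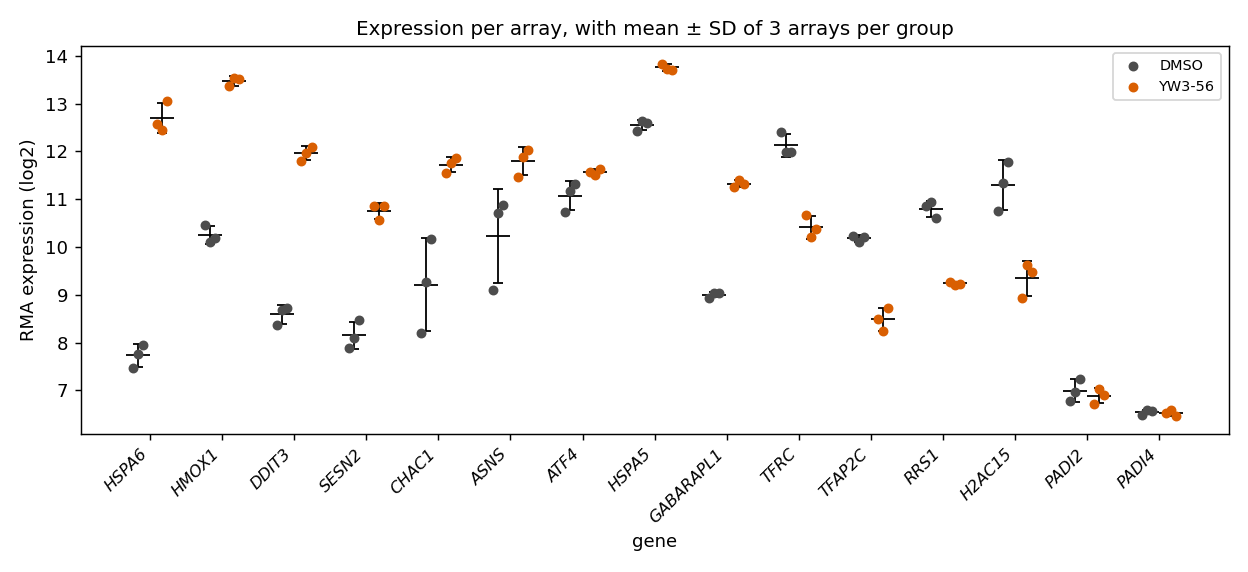
RMA expression on the log2 scale (y axis) of 15 named genes (x axis) in each array, DMSO grey and YW3-56 orange, with bars for mean and SD of 3 arrays. HSPA6 rose from a mean of 7.73 to 12.69, ASNS shows the wide DMSO spread given in the text, and PADI2 and PADI4 lie near 7 in both groups.

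ATF4 is the transcription factor of the integrated stress response, and the list for both rose as a group. The list includes ATF4 itself, so not every member is its target. Of 31 measured members, 23 rose, 0 fell and 8 did not pass, with a median log2 fold change of 1.02 (camera adjusted p = 1.4e-19; adjusted p = 0.195 with an estimated correlation). The counts adjusted over the list alone were 24 higher and 1 lower. Examples beyond DDIT3, SESN2 and CHAC1 were DDIT4, an mTORC1 inhibitor (2.17 ± 0.24), and TRIB3, a pseudokinase (1.97 ± 0.13). ATF4 itself rose by 0.49 ± 0.14 in its brighter probe set, 8180337, at an adjusted p of 0.042, while its other probe set, 8073148, went the other way at -0.54, and their mean changed by -0.02. The ATF4 call was lost when DMSO replicate 2 or any YW3-56 array was left out, with adjusted p of 0.0814 without DMSO replicate 2 and 0.104, 0.0884 and 0.142 without YW3-56 replicates 1, 2 and 3, and its change was 0.32 without DMSO replicate 1. It was also lost in a per-gene test without shared variance (0.295).

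Genes of amino acid synthesis and transport also moved upward, with 13 of 22 measured members higher, 1 lower and 8 not past the threshold (median 0.47; camera adjusted p = 4.7e-08; adjusted p = 0.322 with an estimated correlation). Adjusted over the list alone, 17 rose and 1 fell. CTH, which makes cysteine from cystathionine, rose by 2.01 ± 0.10, the glycine transporter SLC6A9 by 1.46 ± 0.27 and the neutral amino acid transporter SLC1A4 by 1.30 ± 0.19. A per-gene test without shared variance ended the calls of SLC6A9 (adjusted p = 0.164) and SLC1A4 (0.0724). The member that fell was ALDH18A1 (-0.50), an enzyme of proline synthesis. ASNS, asparagine synthetase, rose by 1.57 ± 0.42 (adjusted p = 0.031), and its 3 DMSO values of 9.09, 10.71 and 10.87 were far apart. Without DMSO replicate 1 its change was 1.00 with an adjusted p of 0.0019, and without YW3-56 replicates 1, 2 or 3 its adjusted p was 0.0538, 0.0904 and 0.113. The ASNS call was also lost with a trended and robust prior (0.0618) and in a per-gene test without shared variance (0.288). Of 19 cytosolic aminoacyl-tRNA synthetases, which load amino acids onto tRNAs, 4 rose, 1 fell and 14 did not pass (camera adjusted p = 0.259). Adjusted over the list alone, 6 rose and 4 fell, and the median of -0.00 and the mean of 0.10 differ in sign. AARS1 (0.90 ± 0.11) and WARS1 (0.62 ± 0.11) rose most, joined by GARS1 (0.51) and IARS1 (0.28). VARS1 was the member that fell (-0.34), a call lost without DMSO replicate 2 (adjusted p = 0.0831) and without YW3-56 replicate 2 (0.0935) or 3 (0.0821), and GARS1 was lost without YW3-56 replicate 3 (0.0637). Centring of each array ended the call of VARS1 too (0.0506). The per-gene test without shared variance also ended the calls of VARS1 (0.0898), AARS1 (0.0823), WARS1 (0.133) and GARS1 (0.158).

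Chaperones of the endoplasmic reticulum (ER) and the ER degradation machinery rose in 20 of 25 measured members, and none fell (median 0.80; camera adjusted p = 1.9e-17; adjusted p = 0.195 with an estimated correlation). When adjusted over the list alone, 21 rose and 0 fell. DNAJB9, an ER co-chaperone, rose by 2.23 ± 0.09, HERPUD1, a part of the degradation complex, by 1.71 ± 0.17, and DNAJC3 by 1.43 ± 0.10. HSPA5, the main ER chaperone BiP, was already bright in DMSO (12.56 ± 0.11 SD, n = 3) and was 2.30-fold higher in YW3-56 (13.76 ± 0.07). In the heat shock list, 16 of 17 measured genes rose and 0 fell, with the same 16 and 0 adjusted over the list alone (median 0.66, camera adjusted p = 6.8e-17, adjusted p = 0.195 with an estimated correlation). The list was drawn up as cytosolic, but the mitochondrial chaperones HSPD1 and HSPE1 are among its fixed members. The HSP70-related HSPA1L (1.82 ± 0.09), the co-chaperone DNAJB1 (1.60 ± 0.12) and BAG3, which links chaperones to autophagy and was 2.82-fold higher, were the leading members after DNAJB4. HSPA1L had a mean of 7.54 over all arrays, below the median of 8.20 for tested genes. The caution given for HSPA6 about probes shared between HSP70 genes applies to HSPA1L too.

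Genes of the list for NRF2, the transcription factor that responds to oxidants and electrophiles, rose in 12 of 24 measured members, and 0 fell (median 0.35, camera adjusted p = 2.4e-11, adjusted p = 0.195 with an estimated correlation). The list was fixed with NFE2L2, the gene of NRF2 itself, among its members. Adjusted over the list alone, 14 rose and 0 fell. HMOX1 led, followed by GCLC, the catalytic subunit for glutathione synthesis (1.32 ± 0.08), SRXN1, sulfiredoxin (1.29 ± 0.11), and OSGIN1, which was 2.30-fold higher. NQO1, often used as an NRF2 marker, did not pass, with a log2 fold change of 0.19. Among 9 metallothionein and zinc response genes, 3 rose and 0 fell, also when adjusted over the list alone (median 0.16; camera adjusted p = 0.0014; adjusted p = 0.365 with an estimated correlation). These were the zinc exporter SLC30A1 (0.62 ± 0.12) and the metallothioneins MT1X (0.60 ± 0.08) and MT1E (0.38 ± 0.08), and MT1E was lost without YW3-56 replicate 2 (adjusted p = 0.0543). With replicate number as a block, MT1F (0.33, adjusted p = 0.0467) was called as well. Metallothionein genes are close copies of each other.

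Sterol genes were higher, with 10 of 19 cholesterol synthesis and uptake genes rising and 0 falling (median 0.26; camera adjusted p = 2.7e-07; adjusted p = 0.195 with an estimated correlation). In p-values adjusted over the list alone, 11 rose and 1 fell. HMGCS1, an early enzyme of the pathway, rose by 1.75 ± 0.13, INSIG1, which holds back the sterol sensor, by 1.52 ± 0.14, and STARD4, a sterol carrier, by 1.47 ± 0.09. Fatty acid synthesis genes went both ways, with 4 of 17 higher, 3 lower and 10 not past, also when adjusted over the list alone (camera adjusted p = 0.221). LPIN1 (0.89 ± 0.07), ME1 (0.72 ± 0.09), SCD (0.33) and ELOVL5 (0.29) rose, and ELOVL6 (-0.58 ± 0.09), ACSL1 (-0.53 ± 0.11) and ACACA (-0.37) fell.

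Autophagy genes rose in 12 of 33 measured members and fell in 0 (median 0.19; camera adjusted p = 5.4e-08; adjusted p = 0.195 with an estimated correlation). Adjusted over the list alone, 14 rose and 0 fell. GABARAPL1, a protein of the autophagosome membrane, was 4.97-fold higher (2.31 ± 0.08), well ahead of WIPI1 (1.00 ± 0.08), the cargo receptor SQSTM1 (0.94 ± 0.10) and ATG14 (0.86 ± 0.13). Lysosomal genes rose in 9 of 29 members and fell in 0, with the same counts adjusted over the list alone (median 0.19; camera adjusted p = 1.0e-05; adjusted p = 0.378 with an estimated correlation). The protease CTSL (0.66 ± 0.11) and the cholesterol transporter NPC1 (0.58 ± 0.09) rose most. Regulators of mTORC1, the kinase complex that couples nutrients to growth, rose in 9 of 24 members and fell in 2 (median 0.17; camera adjusted p = 2.5e-04; adjusted p = 0.327 with an estimated correlation). When adjusted over the list alone, 10 rose and 2 fell. Beside SESN2 and DDIT4, the sestrin SESN3 (2.16 ± 0.16) and the folliculin partner FNIP1 (0.94 ± 0.08) rose, while RRAGA (-0.41), a nutrient-sensing GTPase, and RPTOR (-0.36), a subunit of mTORC1, fell.

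**Figure D3:**
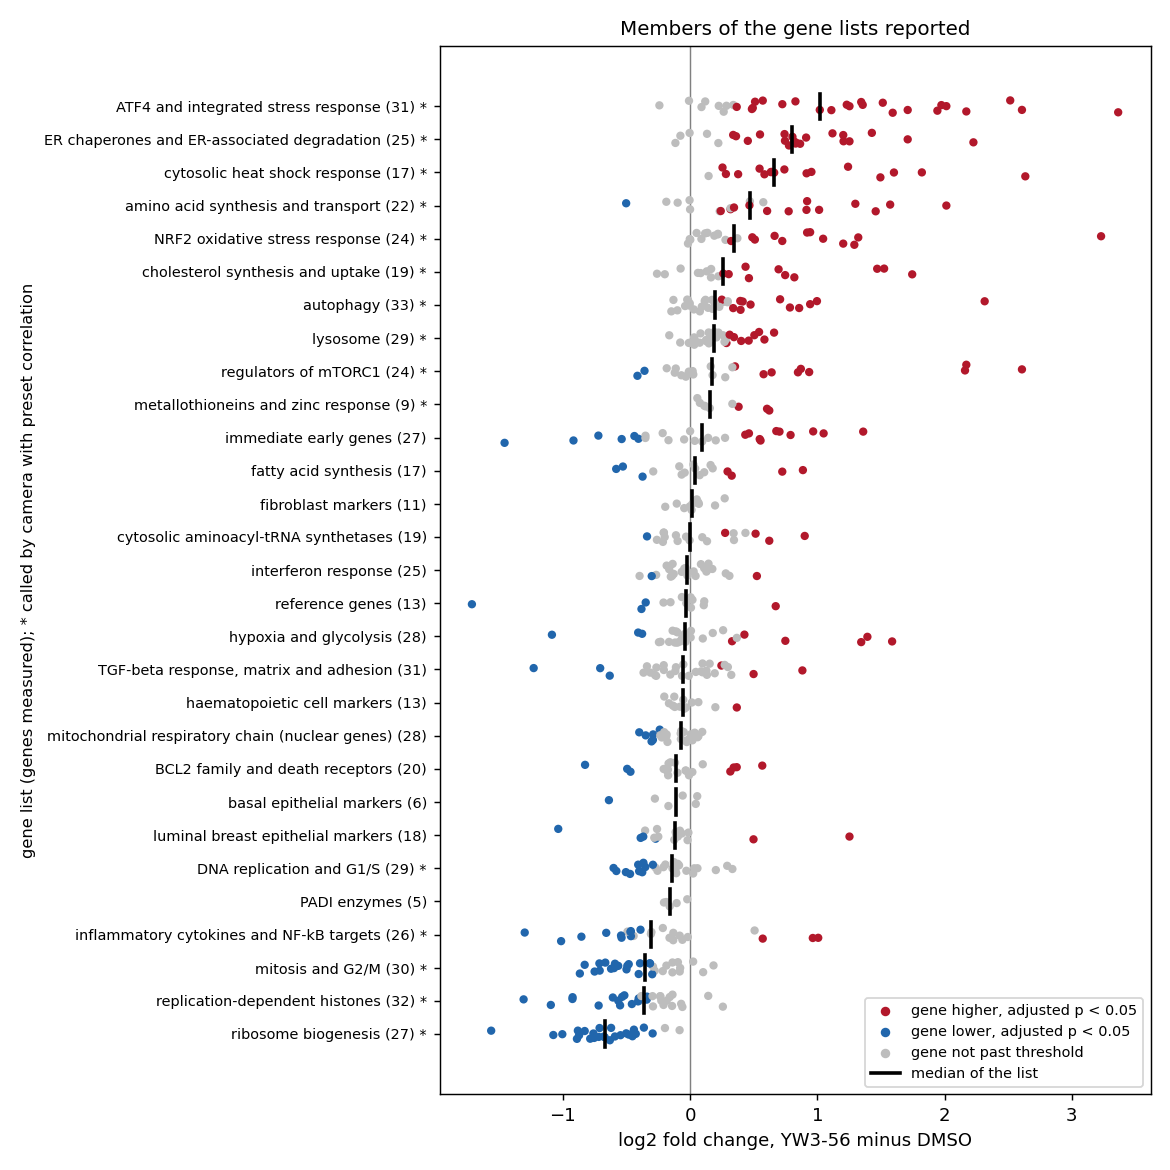
Log2 fold change (x axis, YW3-56 minus DMSO) of the measured members of the gene lists reported here (y axis, number of genes in brackets), 1 point per gene, red for called higher, blue for called lower and grey for not past the threshold. Black bars mark list medians, which run from -0.67 for ribosome biogenesis to 1.02 for the ATF4 list, and asterisks mark lists called by camera with the preset correlation, 0 of which stayed called with an estimated one.

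Ribosome biogenesis genes fell in 25 of 27 measured members, and 0 rose (median -0.67; camera adjusted p = 2.3e-16; adjusted p = 0.195 with an estimated correlation). There were 26 falls adjusted over the list alone. After RRS1, the largest falls were those of MYBBP1A, a nucleolar regulator of rRNA synthesis (-1.07 ± 0.12), UTP20, a processome component that was 2.01-fold lower, and POLR1B, a subunit of RNA polymerase I (-0.89 ± 0.09). FBL (-0.20) and NPM1 (-0.08) were the members that did not pass.

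Mitotic genes fell in 18 of 30 members, and 0 rose (median -0.36; camera adjusted p = 5.4e-08; adjusted p = 0.38 with an estimated correlation). There were 20 falls adjusted over the list alone. TOP2A, topoisomerase II alpha (-0.87 ± 0.08), BUB1B, a spindle checkpoint kinase (-0.83 ± 0.08), and the mitotic kinase PLK1 (-0.75 ± 0.09) led, while CDK1 (-0.08) and MKI67 (-0.21) did not pass. DNA replication and G1/S genes fell in 10 of 29 members by smaller amounts, and 0 rose (median -0.14; camera adjusted p = 0.010; adjusted p = 0.586 with an estimated correlation). Here 1 rose and 11 fell adjusted over the list alone. UHRF1 (-0.60 ± 0.08) and RRM2, a ribonucleotide reductase subunit (-0.58 ± 0.11), fell most, and the list was not called without DMSO replicate 1 (adjusted p = 0.371), with array weights (0.175) or by fry (0.0554). Replication-dependent histone genes fell in 16 of 32 members, and 0 rose (median -0.36; camera adjusted p = 2.3e-06; adjusted p = 0.365 with an estimated correlation). For histones, 18 fell adjusted over the list alone. H2AC4 (-1.31 ± 0.14) and H4C2 (-1.09 ± 0.15) led, with the same caution about near-identical copies.

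In the BCL2 family and death receptor list, 4 of 20 rose and 3 fell, also when adjusted over the list alone (camera adjusted p = 0.727). The pro-apoptotic BCL2L11 (0.57 ± 0.09) and PMAIP1 (0.34), the receptor TNFRSF10B (0.37) and CFLAR (0.32) rose, and TNFRSF10A (-0.83 ± 0.13), BAX (-0.49) and BCL2L1 (-0.47 ± 0.08) fell.

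Inflammatory cytokines and NF-kB targets were lower in 10 of 26 members and higher in 3 (median -0.31; camera adjusted p = 0.024; adjusted p = 0.365 with an estimated correlation). Adjusted over the list alone, 3 rose and 12 fell. The cytokines IL11 (-1.30 ± 0.24) and CSF3 (-1.01 ± 0.15) fell most, whereas PTGS2, the inducible cyclooxygenase (1.01 ± 0.09), NFKBIZ (0.96 ± 0.12) and NFKB2 (0.57) rose. This list lost its call without DMSO replicate 1 (adjusted p = 0.120), with array weights (0.0534) and with filters on dim genes (0.119 and 0.109). Few interferon response genes were called, with 1 of 25 higher and 1 lower (camera adjusted p = 0.547), or 1 and 0 adjusted over the list alone. The median was -0.02 and the mean -0.00. Camera gave an upward direction because it compares a list with the other genes, and the median of all genes tested was -0.05. IRF9 was the member that rose (0.52 ± 0.08), and the fall of PSMB8 (-0.30 ± 0.08) was lost when any array other than DMSO replicate 2 was left out, with adjusted p from 0.0502 without DMSO replicate 1 to 0.124 without YW3-56 replicate 3. PSMB8 was also lost after a second quantile normalization (0.0858), with centring (0.0619) and with a trended and robust prior (0.0535). A per-gene test without shared variance ended the calls of PSMB8 (0.0949) and IRF9 (0.105). With replicate number as a block, IRF7 (0.31, adjusted p = 0.0298) was called higher and OAS3 (-0.40, 0.0121) lower. IRF7 was also called with centring (0.0452), the filter at the median level (0.0454), array weights (0.0115) and without DMSO replicate 3 (0.0183). Immediate early genes were mixed, with 10 of 27 higher and 6 lower, or 10 and 8 adjusted over the list alone (camera adjusted p = 0.146). NR4A2 (1.36 ± 0.10), EGR1 (1.05 ± 0.21) and NR4A3 (0.97 ± 0.14) rose, and IER3 fell (-1.46 ± 0.18).

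Hypoxia and glycolysis genes were split, with 6 of 28 higher and 3 lower, or 6 and 4 adjusted over the list alone (camera adjusted p = 0.318), and the median of -0.04 and the mean of 0.12 differ in sign. KDM3A, a histone demethylase (1.59 ± 0.08), NDRG1 (1.39 ± 0.11) and the angiogenic factor VEGFA (1.34 ± 0.16) rose, while the glycolytic enzymes HK2 (-1.09 ± 0.08) and PFKP (-0.41) and the glucose transporter SLC2A1 (-0.38) fell. Nuclear genes of the respiratory chain were lower in 6 of 28 members and higher in 0, also when adjusted over the list alone (camera adjusted p = 0.126, or 0.0272 without DMSO replicate 3), led by ATP5F1A (-0.40 ± 0.07) and SDHA (-0.35 ± 0.07). In the list of TGF-beta response, matrix and adhesion genes, 3 of 31 rose and 3 fell, or 3 and 7 adjusted over the list alone (camera adjusted p = 0.833). The rises were SKIL (0.88 ± 0.13), SNAI1 (0.50) and CCN2 (0.25), and the falls were the urokinase gene PLAU (-1.23 ± 0.17), its receptor PLAUR (-0.63 ± 0.08) and the integrin ITGA2 (-0.71 ± 0.14).

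Some families defined by their gene symbols were over-represented among the calls. Fisher's test takes genes as independent, so its p-values describe the calls on these arrays and overstate the evidence where genes move together. Zinc finger (ZNF) genes rose in 191 of 495 members, 38.6% against 9.04% of other genes (Fisher's exact test, adjusted p = 5.8e-66), with a median of 0.19. Examples are ZNF93 (1.30 ± 0.18) and ZNF227 (1.25 ± 0.11). Small nucleolar and Cajal body RNA genes fell in 77 of 192 members, 40.1% against 11.2% (adjusted p = 3.8e-23), led by SNORD12C (-2.29 ± 0.12), SNORD75 (-2.09 ± 0.09) and SNORA74A (-2.01 ± 0.11). None of the 16 Cajal body RNA genes among them was called, and 9 of 23 spliceosomal RNA genes (RNU and RNVU) fell. Heat shock and DNAJ genes rose in 35 of 83 (adjusted p = 1.5e-13) and TRIM genes in 13 of 57 (0.0076). Falls were over-represented among histones, with 27 of 70 (3.2e-08), mitochondrial ribosomal proteins, with 25 of 74 (1.8e-06), and RNA polymerase subunits, with 13 of 32 (9.2e-05). The same held for genes with symbols beginning EIF, with 14 of 50 (0.0033). These are called initiation factors here, although the symbol also takes in EIF2AK3. With calls from a per-gene test without shared variance, histones (adjusted p = 0.384), RNA polymerase subunits (0.0635) and initiation factors (0.195) were not enriched among falls. Histones were then called lower less often than other genes. This concerns the calls only, since the fold changes are the same in that test. The initiation factors were also not enriched after centring of the arrays (0.222) or when any single array was left out, with adjusted p from 0.0608 without DMSO replicate 3 to 0.917 without YW3-56 replicate 2. Genes with symbols beginning RPL or RPS were not enriched among falls, which took in 8.91% of them against 11.5% of other genes (adjusted p = 0.624). That set is wider than the cytosolic ribosomal proteins and includes RPL32P3.

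**Figure D4:**
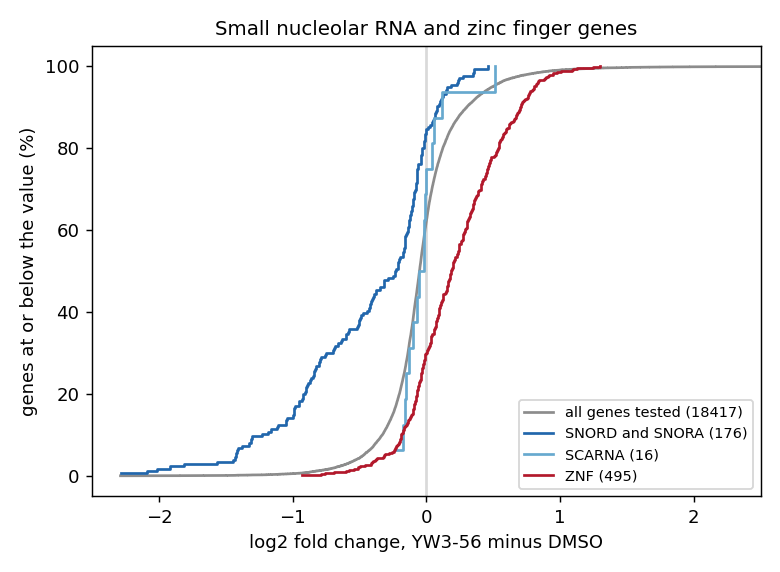
Cumulative share of genes (y axis, percent) at or below each log2 fold change (x axis, YW3-56 minus DMSO, drawn from -2.5 to 2.5) for all 18417 genes, 176 SNORD and SNORA genes, 16 SCARNA genes and 495 ZNF genes. The SNORD and SNORA curve lies left of the curve of all genes, where 77 fell, and the ZNF curve lies right of it, where 191 rose.

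The genes of the enzymes that YW3-56 is known to inhibit were dim on these arrays in both groups. PADI2 had values of 6.79, 6.96 and 7.25 in the 3 DMSO arrays, and PADI4 had a mean of 6.55 ± 0.05 (SD, n = 3). Over all 6 arrays the 5 PADI genes ranked between the 18.2 and 30.5 percentile of tested genes by mean. Their log2 fold changes were -0.16 for PADI1, -0.11 for PADI2, -0.21 for PADI3, -0.02 for PADI4 and -0.19 for PADI6, with adjusted p from 0.196 to 0.883, so limma called 0 of 5 genes, and 0 were called when adjusted over the list alone. None of the 5 had an unadjusted limma p under 0.05, a per-gene test without shared variance called none of them either, and the list as a whole was not called (camera adjusted p = 0.376). The 95% interval of the PADI4 change ran from -0.19 to 0.14.

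Lists of markers of other cell types were not called. Of 18 luminal epithelial markers, 2 were higher and 4 lower, or 2 and 5 adjusted over the list alone (camera adjusted p = 0.154, or 0.0466 downward without XBP1, which the ATF4 list shares). XBP1 (1.25 ± 0.16) and MLPH (-1.04 ± 0.16) changed most. Of 6 basal markers, LAMB3 fell (-0.64 ± 0.12) and 0 rose, also when adjusted over the list alone (camera adjusted p = 0.376). None of 11 fibroblast markers was called by limma over all genes or adjusted over the list alone (camera adjusted p = 0.440), and 1 of them, COL1A1, had an unadjusted p under 0.05. With array weights, COL1A1 (0.28, adjusted p = 0.0339) was called higher and ACTA2 (-0.25, 0.0339) lower, and COL1A1 was also called without DMSO replicate 3 (0.40, 0.0183). Other marker calls gained were KRT15, lower with array weights (0.00541) and without DMSO replicate 1 (0.00881), SPI1, lower in the same settings (0.0346 and 0.0175), CD34, higher after a second quantile normalization (0.0283), and EGFR, lower with the filter at the median level (0.0481) and a trended and robust prior (0.045). Among 13 haematopoietic markers, HBB alone was called, in both adjustments (0.37 ± 0.09; camera adjusted p = 0.869), and the HBB call was lost when any array other than DMSO replicate 1 or YW3-56 replicate 2 was left out, with adjusted p from 0.0568 without DMSO replicate 3 to 0.0781 without YW3-56 replicate 3. The median of the haematopoietic list was -0.05, as was that of all genes tested, and the camera direction, which is relative to other genes, was upward.

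Of 13 reference genes, 1 rose and 3 fell, with the same counts adjusted over the list alone (camera adjusted p = 0.524). POLR2A rose (0.67 ± 0.09), and TFRC, IPO8 (-0.38 ± 0.08) and SDHA fell, with IPO8 lost without YW3-56 replicate 3 (adjusted p = 0.0594). GAPDH (0.00), PGK1 (0.01) and ACTB (-0.06) did not pass. The list of short-lived and processed RNAs had 4 measured members, too few for a list test. MALAT1, a nuclear long RNA, rose (0.88 ± 0.13) and TAF1D fell (-0.48 ± 0.09).

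In all, camera with the preset correlation called 16 of 30 lists, 11 upward and 5 downward. With the correlation estimated from the 6 arrays it called 0 after adjustment and 6 at an unadjusted p under 0.05, while fry called 19 for a shift in 1 direction, adding BCL2 family, immediate early, hypoxia, respiratory chain and fatty acid genes and losing lysosome and G1/S genes.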

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

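Probe sets outside the gene-level comparison were examined because they carried differences between the groups. Among 1754 probe sets assigned to several genes, 274 changed at an adjusted p under 0.05 in limma, 139 higher and 135 lower in YW3-56. Among 12083 probe sets with no gene listed in the annotation used, 635 changed, 249 higher and 386 lower. Control probe sets of the array were not separated from these and may be among them. The largest rises were those of probe sets 7906775 (log2 fold change 2.96 ± 0.17) and 8179322 (2.81 ± 0.09), both assigned to several genes. The largest falls were those of probe sets 8053646 (-2.52 ± 0.25) and 7912525 (-2.24 ± 0.23), neither with a gene listed. Both were dim, with means over the 6 arrays of 6.57 and 4.54, so the size of these falls is uncertain. No gene is named for these, and no explanation for them was tested.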

How the results depend on the processing

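Of 2012 values for named genes under alternative settings, 1873 kept their side of the threshold, 6 of them uncalled values that changed sign, 120 lost the call, 70 of them with Welch's test, and 18 gained one. Of the 116 called named genes, 46 kept the call in every setting. Of 530 values for lists, 499 kept their side, 11 of them uncalled with a change of sign, 24 lost the call and 7 gained one, and of 136 for families, 123 kept direction and side and 12 lost the call. The 1 reversal among named genes was ATF4, which changed by -0.023 when its probe sets were averaged. The 1 reversal among families concerned histones, which with Welch's test were called lower less often than other genes (adjusted p = 0.384). Their fold changes were the same in that test. Welch's test also ended the call of RNA polymerase subunits (0.0635). The cause of neither reversal was tested beyond the opposite signs of the ATF4 probe sets.

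Counts of changed genes depended on how the variance was estimated and on which arrays were included. With array weights, 6079 genes were called, 3432 of them lower. DMSO replicate 2 then carried most of the weight of its group (2.94, against 0.33 and 0.65), so calls gained there lean on that array. The cause of the higher count was not tested. Welch's test, which shares no variance between genes, called 1130 genes, 534 higher and 596 lower, with 152 at 2-fold and 5 families enriched. At an adjusted p under 0.01 there were 2129 calls, 1054 higher and 1075 lower. With 1 array left out, calls ran from 2364 to 4689, rises from 1158 to 2084 and falls from 1206 to 2605, where the low values came without YW3-56 replicate 3 and the high ones without DMSO replicate 1. At 2-fold, 413 probe sets passed when each of the probe sets was tested, which adds those without a single gene, and 1044 genes passed treat at 1.2-fold, a lower bound on size. The balance of directions turned with scaling: quantile normalization gave 4211 calls, 2120 higher and 2091 lower, 3763 of them shared, and centring gave 3641, 1899 higher and 1742 lower, 3530 of them shared. The mean correlation within groups was 0.992 without the dimmest genes and 0.990 among genes above the median level.

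With an estimated correlation, 0 of the 16 lists stayed called. The adjusted p was 0.195 for the ATF4, ER, cholesterol and autophagy lists, 0.322 for amino acid genes, 0.378 for lysosomal genes and 0.327 for mTORC1 regulators. Fry gave 0.0531 for lysosomal genes and, for change in either direction, called 27 lists. The replicate block gave 4776 calls, 3896 of them shared, added calls for IRF7, MT1F and OAS3 and changed no other call of a named gene, list or family. Welch's test was not run for lists. Array weights estimated by REML did not converge, and gene-by-gene weights were used. Signal close to background limits what can be said of dim genes such as the PADI genes.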

Other observations

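Some genes known to restrain growth were among those higher in YW3-56, but no set of such genes was tested. They were chosen after their values were seen and are described as values. MXD1, an antagonist of MYC, was 3.24-fold higher in YW3-56 (log2 fold change 1.70 ± 0.08 SE, limma adjusted p = 2.8e-05), and HBP1, a repressor of cell cycle genes, was 3.03-fold higher (1.60 ± 0.11). The antiproliferative genes BTG1 (1.19 ± 0.09) and TOB1 (1.04 ± 0.12), the cyclin CCNG2 (1.24 ± 0.16), the translation inhibitor PDCD4 (1.17 ± 0.07) and the repressor BCL6 (1.01 ± 0.11) rose as well. CCND1, cyclin D1, fell (-0.78 ± 0.14, adjusted p = 0.0056).

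Other genes chosen in the same way belong to the ER, to chromatin, to polyamines, to coagulation and to urokinase and its receptor. EIF2AK3, the ER stress kinase PERK, was 2.83-fold higher, FICD, which modifies BiP, rose by 1.56 ± 0.10, and CREBRF, a regulator of the unfolded protein response, by 1.69 ± 0.08. The histone demethylase genes KDM3A (1.59 ± 0.08), KDM7A (1.43 ± 0.12) and KDM4A (1.11 ± 0.09) and the related JMJD1C (1.02 ± 0.08) rose. SAT1, which breaks down polyamines, rose 6.12-fold, and ODC1, the first enzyme of their synthesis, fell (-0.47 ± 0.11, adjusted p = 0.018), while SMOX (0.34, adjusted p = 0.0729) and SRM (-0.21, 0.06) did not pass. Tissue factor, F3 (-1.66 ± 0.18), and the thrombin receptor F2R (-1.19 ± 0.13) fell, as did the urokinase gene PLAU and its receptor PLAUR.

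Of the tests that follow, those of short RNA loss, of all small nucleolar RNAs against their hosts, of those without a measured host, of an exchange of DMSO replicate 1 with a treated array and of shared handling were chosen after the result was seen.

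Small nucleolar RNAs fell, 77 of 176 SNORD and SNORA genes, while 0 of 16 SCARNA genes did. Signal from the host transcripts was compared where a host was measured, with hosts assigned by position alone. Over all 85 such RNAs, not selected by their change, the RNA lay below its host by a mean of -0.28 over 65 hosts (two-sided permutation of signs over hosts, 100000 permutations, p = 9e-05). The RNA lay below in 40 of the 65, with medians of -0.17 for the RNAs and -0.08 for the hosts. The permutation takes hosts as independent and leaves the arrays in place. Its p-value therefore does not measure variation between cultures and overstates the evidence where these RNAs move together. On these arrays the differences argue against the measured host level as the whole cause, but unspliced host transcripts were not measured separately. Hosts of the fallen RNAs had a median of -0.14, a contrast partly fixed by choosing RNAs that fell. Of these 27 hosts 10 fell and 0 rose, so a part may come from the host, and for 38 fallen RNAs without a measured host this stays open. A loss of short RNAs during extraction also stays open, because SCARNA genes are longer (median 226.5 bases against 94), among genes of 120 to 140 bases 19 of 55 fell against 0 of 6 SCARNA genes (two-sided Fisher's exact test, p = 0.164), and other short classes moved apart, with 9 of 23 RNU and RNVU genes lower (median -0.40) but 4 of 189 MIR genes lower and 15 higher (median -0.03). A response of these RNAs to the compound was not separated from that loss.

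Zinc finger genes rose in large number with small changes. The median level of these genes over all arrays was 8.29, against 8.20 for all genes tested. As a class they were thus not dim, which argues against low signal as the cause for the set. Their median change also lay above all 10000 random lists matched on mean level (percentile 100). Many zinc finger genes lie in clusters of close paralogs on chromosome 19, where 116 of 237 rose. The 258 on other chromosomes also had a median above all matched lists (percentile 100), with 75 higher and 16 lower. Probes shared only within those clusters are thus argued against as the whole cause. Sharing of probes between chromosomes was not tested, and the matched lists ignore correlation between genes. The rise was more frequent on chromosome 19 (two-sided Fisher's exact test, p = 5.9e-06), and other genes of that chromosome had a median of -0.07. A broad rise of this class after the compound may be biological, as a hypothesis only, and the part that shared probes add on chromosome 19 was not measured.

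DMSO replicate 1 stood apart from the other DMSO arrays, and ASNS was lowest there. The stress genes were graded over the DMSO arrays, with DMSO replicate 3 on the other side. In DMSO replicates 1, 2 and 3 the amino acid list deviated from the DMSO mean by -0.21, 0.03 and 0.18. CHAC1 had values of 8.21, 9.26 and 10.16 there. An exchange of DMSO replicate 1 with a treated array is argued against. On 4689 genes called without DMSO replicate 1, that array lay at 0.0988 of the way from the other DMSO arrays to the treated mean. An array-wide difference in scale is argued against as the whole cause, because after centring the amino acid list lay below all matched lists in this array (percentile 0, median deviation -0.13). Shared handling of the arrays numbered 1 has the correlation of deviations it needs, 0.539 with YW3-56 replicate 1, and may contribute, for instance through medium or cell density. No biological explanation was tested, since the labels name no difference between these cultures.

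The 6 arrays can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split gave 3933 changed genes, 262 at 2-fold and 16 lists, and the highest of the other splits gave 0, 0 and 14. As large a result came from 1 of 10 splits, the real one, for each count. Each of the other splits keeps a part of the difference between the groups, and they called between 8 and 14 lists by camera with the preset correlation.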
